A study of Homo sapiens with 5 samples.

How the data were processed

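RNA was taken from LX-2 human hepatic stellate cells 48 h after transfection with control siRNA (2 libraries) or LIX1L siRNA (3 libraries), and libraries were made by a standard Illumina protocol, per the labels' protocols. The sequences and the number of the siRNAs, the strandedness of the kit and any batch are not given in the sources used here. Samples were grouped by the siRNA in their labels.

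The authors deposited 1 file per library with FPKM for 19936 genes under human Ensembl IDs, per the file headers. The file of siLIX1L 3 alone also holds a deposited gene length and the authors' raw read count per gene. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8, a mouse build, which does not match the human IDs; the build, the counting tool and the annotation are therefore uncertain. Bowtie of that version does not align reads across splice junctions, so reads over exon borders may be missing. The lengths are equal to gene spans, introns included, of GENCODE 29 on GRCh38 for 19567 of the 19926 genes found there (98.2%), and coordinates are given on that annotation. The median length is 27.0 kb, against 2.94 kb for the longest transcript, so the FPKM of genes with long introns is low compared with values per kilobase of mRNA; a comparison of the same gene between libraries is not affected, apart from the minimum level and the pseudocount.

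FPKM times length was a whole multiple of 1 step in each library, to a tolerance of 0.01 reads, for 100% of values, and the reads recovered in this way were equal to the authors' deposited counts for all 19936 genes of siLIX1L 3. The recovered totals, 14856104 to 18294056 reads, give the depth. RPM, reads per 1000000, is relative to these totals. A count of 0 allows up to 3 reads, worth 0.164 to 0.202 RPM. Mitochondrially encoded genes took 2.24 and 3.35% of reads in control 1 and 2 and 1.08, 1.29 and 1.14% in siLIX1L 1, 2 and 3. SiLIX1L 1 and 2 had a chi-square per gene of 5.38 between them, against 52.7 or above in every other pair, which does not show that they are separate cultures; they were kept as 2 replicates as labelled.

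The main test was limma 3.58.1 (R 4.3.3; linear model, eBayes with trend and robust, two-sided, Benjamini-Hochberg, threshold 0.05) on log2(FPKM + 1), without covariates, over 6464 genes with at least 1 FPKM in at least 2 libraries. The design had foreseen either counts or normalized values; since the unit common to all files is FPKM, the branch for normalized values was used. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests a list's genes without reference to other genes. Lists with fewer than 5 measured members were described only. Fold changes in plain numbers are ratios of mean RPM.

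The test, the lists, the rule for named genes and the alternatives were fixed before the data were examined. Named are LIX1L and CCL20; the 10 highest and 10 lowest log2 fold changes past the threshold with groups that do not overlap and a mean of at least 2 FPKM; in each list up to 4 members past the threshold with the smallest p or, with none, up to 2 others given as values; and COL1A1, COL1A2, ACTA2, TIMP1, CCL2, IL6 and CXCL8; 1 gene that this rule names is not reported here. The settings varied were no minimum level, a minimum of 5 FPKM, median-ratio scaling, quantile normalization, a pseudocount of 0.1, the replicate number as a block and each library left out. EdgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads, siLIX1L 1 and 2 averaged, and removal of a loess trend on transcript length and GC content (span 0.5) were added after seeing the data.

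The heptamer scan, also added after seeing the data, used the longest coding transcript of each gene in GENCODE 29 with at least 30 bases of 3′ UTR (12885 genes) and the 15960 heptamers found in at least 100 of these 3′ UTRs. The difference in log2(RPM + 0.5) between 2 libraries was regressed on presence of the heptamer, with log2 3′ UTR length, 3′ UTR GC content, log2 transcript length, mean level and their squares as covariates. Genes are not independent, so z was used to rank heptamers, not as a p-value. It was run in Python 3 with numpy and scipy.

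Each step was tested on simulated data. With reads drawn for the real genes of the siLIX1L against control comparison, limma (6372 genes tested) recovered 33% of 2-fold and 98% of 4-fold changes, with 12 false of 143 calls. EdgeR (13071 genes) recovered 29% and 100%, and DESeq2 (16581 genes) 46% and 100%. The simulated libraries were independent, with the same spread of a gene in all of them and no length trend. The real siLIX1L 1 and 2 were far closer to each other than other pairs. These rates of recovery and false calls may therefore not hold for the real data. A list of 30 genes changed by 1.5-fold was found at both correlations, and 0 of 20 unchanged lists were called. Its camera adjusted p was 3.97e-16 at the preset correlation but 0.0492 with the estimated one, close to the threshold. Missing the threshold with an estimated correlation therefore does not show that a list is unchanged. The reads were drawn for each gene separately and the unchanged lists were random genes. False calls at the preset correlation in lists whose genes move together were therefore not tested. The estimated correlation was 0.65 in the interferon list and 0.80 in the ribosomal list. The scan ranked a planted heptamer of effect -0.15 first, with a coefficient of -0.12.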

Results

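RNA of LX-2 cells, an immortalised line of human hepatic stellate cells, the liver cells that produce most scar matrix, was sequenced 48 h after transfection with a small interfering RNA (siRNA). There were 2 libraries with control siRNA and 3 with siRNA against LIX1L, a gene whose product has a predicted double-stranded RNA-binding domain. The series title ties LIX1L to the stability of the mRNA of CCL20, a chemokine, and to fibrosis, and the comparison asks how the transcriptome of these cells changed with less LIX1L. Each library holds values for 19936 human genes. The reads counted over these genes were 14877647 and 18294056 in control 1 and 2, and 14856104, 15103292 and 17811940 in siLIX1L 1, 2 and 3. Levels are given as the deposited FPKM or as RPM, reads per 1000000 of these totals. Genes with 1 read or more numbered 15374 and 15724 in the controls and 15238, 15219 and 15384 in the siLIX1L libraries. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

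LIX1L itself (ENSG00000271601, GRCh38 chromosome 1, 145933423 to 145958001, minus strand) was lower in each of the 3 siLIX1L libraries than in both controls. Its level was 1.26 ± 0.26 FPKM (SD, n = 2) in the controls and 0.24 ± 0.08 FPKM (SD, n = 3) after LIX1L siRNA. In reads, it had 393 and 649 in the controls and 98, 107 and 65 in siLIX1L 1, 2 and 3. The level in RPM, 5.56-fold lower over the pooled reads, has an exact 95% interval of 4.86 to 6.38, which covers counting error only. On the log2(FPKM + 1) scale, which understates the change of low genes, LIX1L fell by 0.87 (SE 0.11, limma adjusted p = 0.0384). The call was lost when any 1 siLIX1L library was left out (adjusted p = 0.0759 to 0.230 in limma), with unchanged direction. An antisense gene overlaps LIX1L in the annotation and no source used here says whether strand was kept, so reads of the antisense gene could not be separated.

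CCL20 (ENSG00000115009, GRCh38 chromosome 2, 227805739 to 227817564), which encodes a ligand of the receptor CCR6, had few reads in the controls. It was lower after LIX1L siRNA, where it was close to the lower end of detection. It had 74 and 56 reads in the control libraries and 4, 5 and 1 in siLIX1L 1, 2 and 3. Its mean was 4.02 ± 1.35 RPM (SD, n = 2) against 0.219 ± 0.144 (SD, n = 3). Over the pooled reads, 130 in the controls and 10 after LIX1L siRNA, it was 18.7-fold lower, with an exact 95% counting interval of 9.86 to 40.0. In FPKM the means were 0.34 ± 0.11 (SD, n = 2) and 0.0185 ± 0.0122 (SD, n = 3), a difference of -0.39 on the log2(FPKM + 1) scale. FPKM was computed here over the whole gene with its introns, so CCL20 lay under the minimum of 1 FPKM in 2 libraries that was set before the data were examined, and the limma test does not cover it. On the recovered reads, a test added after the data were seen, edgeR gave a log2 fold change of -4.20 with adjusted p = 0.0425, and DESeq2 gave -4.23 with adjusted p = 1.59e-06. Without the minimum, limma gave adjusted p = 0.103 for CCL20.

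**Figure D1:**
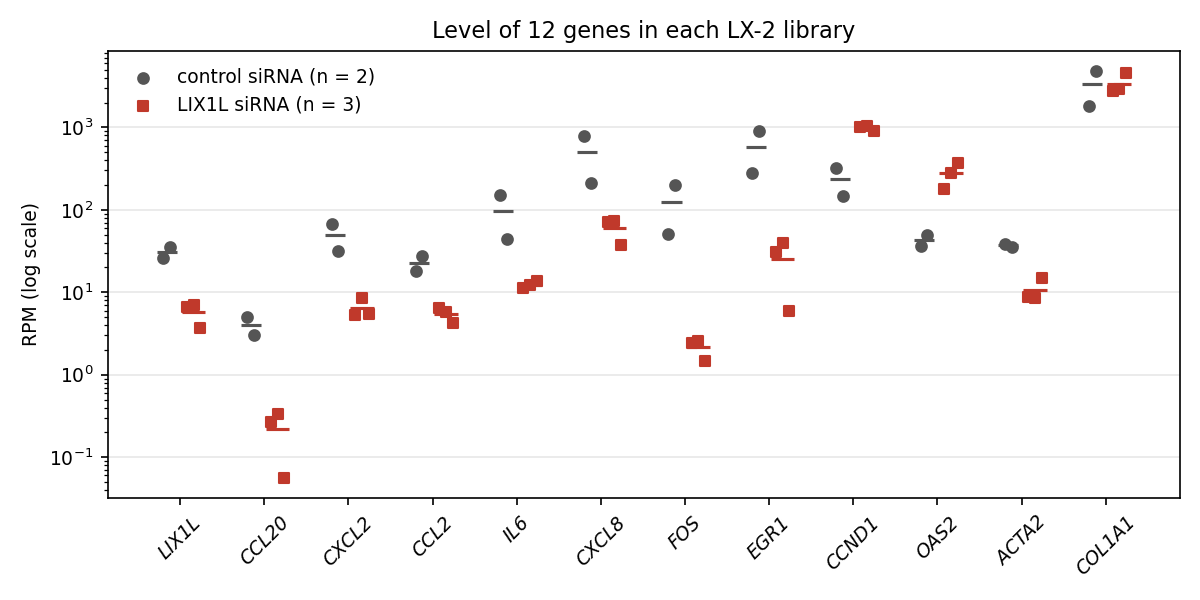
RPM (vertical log axis) of 12 named genes in each of the 5 LX-2 libraries, with circles for the 2 control siRNA libraries, squares for the 3 LIX1L siRNA libraries and short lines for group means. LIX1L, CCL20, CXCL2, CCL2, IL6, CXCL8, FOS, EGR1 and ACTA2 lie lower in all 3 siLIX1L libraries than in both controls, CCND1 and OAS2 lie higher, and COL1A1 overlaps between the groups.

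Across the 6464 genes tested, 121 passed limma's adjusted p of 0.05: 48 rose and 73 fell after LIX1L siRNA. In all 121 the 2 control libraries lay entirely to 1 side of the 3 siLIX1L libraries, a separation seen in 46.5% of all genes tested. By chance it is seen in 20% if all libraries are interchangeable. SiLIX1L 1 and 2 were far closer to each other than any other pair, so 20% may be too low. The largest falls among the better expressed of these genes were in EGR1 and FOS, transcription factors that cells induce within minutes of a stimulus. EGR1 went from 153 ± 114 to 6.67 ± 4.57 FPKM (22.9-fold lower in RPM) and FOS from 36.0 ± 30.2 to 0.623 ± 0.176 FPKM (57.8-fold lower). The other 8 of the lowest 10 were CXCL2, FOSB, MDK, ADM, RARRES2, CLDN11, DUSP1 and TXNIP. MDK, the growth factor midkine, was 4.49-fold lower, RARRES2, the chemoattractant chemerin, 9.02-fold, the tight junction gene CLDN11 4.93-fold, and TXNIP, an inhibitor of thioredoxin, 3.47-fold. On the log2(FPKM + 1) scale of the test the 10 largest rises ran from CCND1, which encodes cyclin D1, at 17.6 ± 9.25 against 73.1 ± 5.89 FPKM (4.16-fold), to TPRG1L at 12.4 ± 0.299 against 30.3 ± 0.448 FPKM (2.45-fold). Between them on that scale were OAS2 (6.50-fold, the highest ratio), CCN3 (3.08-fold), the metallothionein MT1E (3.02-fold), SAMD9 (2.95-fold), SKP2 (3.18-fold), EFCAB14 (3.38-fold), ADAR (2.75-fold) and TRIM25 (2.91-fold). The ratios of 6 of the 32 named genes past the threshold moved by over 1.5 times without 1 control. EGR1 was 35.1-fold lower without control 1 and 10.8-fold without control 2, and FOS 92.1-fold and 23.5-fold. CXCL2 was 4.97-fold lower and CCND1 6.62-fold higher without control 1, and FOSB 5.79-fold and ADM 2.85-fold lower without control 2. All SDs are over n = 2 controls and n = 3 siLIX1L libraries.

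SiLIX1L 1 and 2 were far closer to each other (biological coefficient of variation 6.30%) than to siLIX1L 3 (22.2% and 22.3%) or than the controls were to each other (35.01%). Control 1 was closer to each siLIX1L library (31.0 to 32.4%) than to control 2. The count of genes past the threshold was 0 in limma without any 1 of the siLIX1L libraries or with siLIX1L 1 and 2 averaged, where 899 to 1773 genes passed an unadjusted p under 0.05, and it was 1650 without control 1 and 337 without control 2. EdgeR on the recovered reads called 116 genes, 50 higher and 66 lower, of which 77 were among the 121; DESeq2 called 1673. Of the 32 genes named here as past limma's threshold, EGR1, SKP2, FBN1, COL6A2, MMP19, DDB2 and NT5E (7 genes) did not pass with edgeR (adjusted p = 0.0502 to 0.0558). Quantile normalization gave 233 calls. With a trend of the values on transcript length and GC content removed, 2 genes passed, and without the minimum level none did (3407 at an unadjusted p under 0.05). All 121 genes kept their direction in each setting that tested them.

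**Figure D2:**
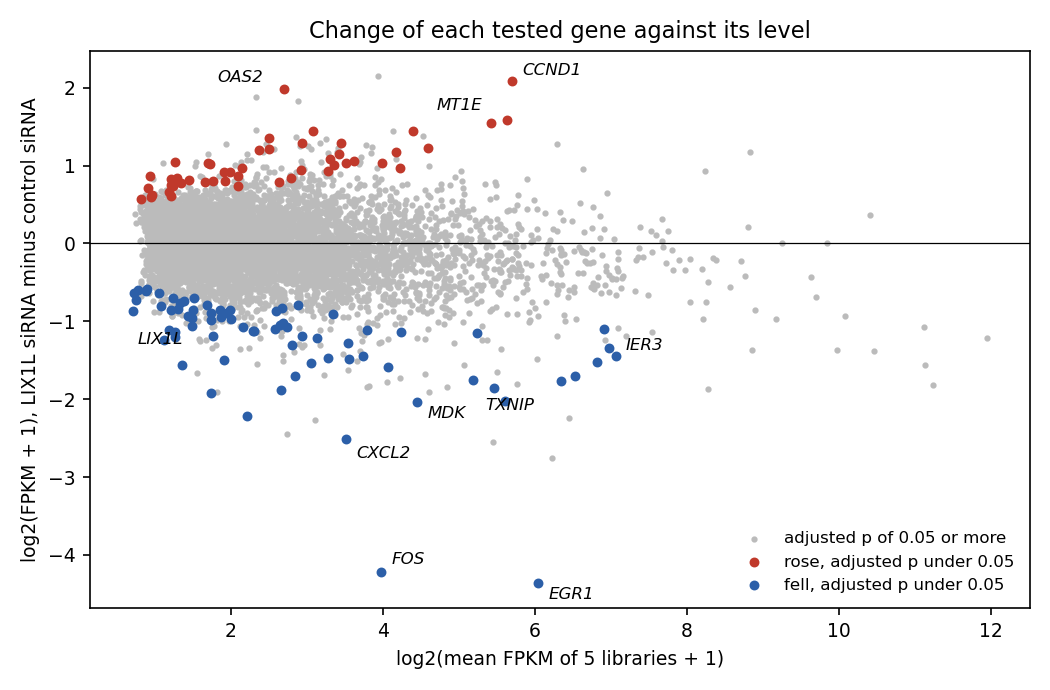
Difference in log2(FPKM + 1) between LIX1L siRNA and control siRNA (vertical axis) against the log2 of the mean FPKM plus 1 over 5 libraries (horizontal axis) for the 6464 genes tested. Coloured points are the 48 genes that rose and the 73 that fell at limma's adjusted p under 0.05, with EGR1 and FOS lowest.

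Of 27 gene lists fixed before the data were examined, 24 had 5 or more measured members, and 12 of these passed limma's camera test at its preset correlation between genes, 10 lower and 2 higher after LIX1L siRNA. None of the 12 held with a correlation estimated from these libraries, where the adjusted p of the 24 lists was 0.314 or above. With fry, which asks only whether a list's genes move on balance in 1 direction, chemokines, DNA replication and immediate early genes passed (adjusted p = 0.0451 for each).

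Chemokines and their receptors were lower as a list, with negative differences in all 9 measured members (adjusted p = 8.51e-05 by camera, and adjusted p = 0.314 with an estimated correlation). CXCL2 and CCL2, which attract neutrophils and monocytes, fell, 5 members fell adjusted over the list alone, and 7 did not pass over all genes. Of the 17 members with enough reads for edgeR, 14 had negative and 3 positive differences. Without the minimum level the list's camera adjusted p was 0.0182. CXCL2 went from 21.9 ± 11.0 to 2.84 ± 0.817 FPKM (limma adjusted p = 0.0384, 7.72-fold lower), and CCL2 from 11.4 ± 3.26 to 2.76 ± 0.591 FPKM (limma adjusted p = 0.0384, 4.12-fold lower). CXCL8, or interleukin 8, was 157 ± 128 against 18.8 ± 6.15 FPKM and did not pass (limma adjusted p = 0.0556). The controls differed between themselves in it, with 248 and 66.5 FPKM. CXCL1, CXCL2 and CXCL3 are near-identical, and how shared reads were counted is not given in the sources used here.

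NF-κB targets and inflammatory cytokines were lower in 18 of 22 measured members (camera adjusted p = 1.10e-04, and adjusted p = 0.314 with an estimated correlation). Over members with enough reads for edgeR, the median deviation of log2 RPM from each gene's mean was 0.69 in control 1 but -0.09 in control 2. In siLIX1L 1, 2 and 3 it was -0.40, -0.39 and -0.15. IER3, a survival gene that also belongs to the immediate early list, fell from 215 ± 34.2 to 77.7 ± 1.82 FPKM (limma adjusted p = 0.0384), and 21 did not pass, while 10 fell adjusted over the list alone. IL6, which encodes interleukin 6, was 16.01 ± 12.5 against 2.02 ± 0.197 FPKM, with 24.8 FPKM in control 1 and 7.19 in control 2. It missed the limma threshold (adjusted p = 0.0536) and passed it with edgeR on the recovered reads (adjusted p = 0.0465). Immediate early genes were lower in 16 of 25 members, 6 of which fell, among them FOS, FOSB, EGR1, DUSP1 and IER3 (camera adjusted p = 0.00776; adjusted p = 0.314 with an estimated correlation). FOSB was 10.4-fold and DUSP1, a phosphatase of MAP kinases, 3.77-fold lower. Adjusted over the list alone, 10 immediate early genes fell and 2 rose. Without control 1 the list no longer passed (adjusted p = 0.0635 by camera). Control 2 held more FOS and EGR1 than control 1, at 57.4 against 14.6 FPKM for FOS and 234 against 72.2 FPKM for EGR1.

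Type I interferon response genes were higher as a list, with positive differences in 30 of 34 members (camera adjusted p = 1.23e-07; adjusted p = 0.638 with an estimated correlation). OAS2 and SAMD9 rose and 32 did not pass; adjusted over the list alone, 22 rose and 2 fell. OAS2, which senses double-stranded RNA, went from 1.29 ± 0.275 to 8.35 ± 2.91 FPKM (limma adjusted p = 0.0384), and SAMD9, an antiviral factor, from 9.25 ± 0.882 to 27.3 ± 5.25 FPKM (limma adjusted p = 0.0384). Over 38 members with enough reads for edgeR, the median deviation of log2 RPM from each gene's mean was -0.67 and -0.58 in the controls and -0.01, 0.35 and 0.89 in siLIX1L 1, 2 and 3. Of the 21 measured genes of cholesterol synthesis and uptake, 18 had positive differences and none passed by itself (camera adjusted p = 7.50e-04; adjusted p = 0.638 with an estimated correlation). STARD4 was 5.13 ± 0.770 against 10.6 ± 1.18 FPKM (limma adjusted p = 0.0503). This list did not pass without control 1 (camera adjusted p = 0.138).

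Genes of DNA replication and S phase were lower in 31 of 32 members (camera adjusted p = 6.05e-08; adjusted p = 0.314 with an estimated correlation). TK1, thymidine kinase, fell from 27.0 ± 1.04 to 11.8 ± 1.34 FPKM (limma adjusted p = 0.0384), 19 members fell and 1 rose adjusted over the list alone, and the exception was CCND1, which acts in G1 and rose. Genes of G2/M and mitosis did not pass as a list (camera adjusted p = 0.428), though they did, lower, with the length and GC trend removed (adjusted p = 0.0293, and 0.818 with an estimated correlation); the 2 with the smallest p were UBE2C, at 57.2 ± 0.594 against 31.0 ± 3.04 FPKM (limma adjusted p = 0.0536), and NDC80, at 6.67 ± 0.131 against 3.75 ± 0.390 FPKM (limma adjusted p = 0.0556).

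Of the fibrosis lists, only collagen processing and crosslinking passed, with 14 of 16 members negative and none past the threshold alone (camera adjusted p = 0.0420; adjusted p = 0.638 with an estimated correlation). It passed in 9 of 14 other settings. Without control 2 its direction turned (camera adjusted p = 0.989). PCOLCE, an enhancer of procollagen processing, was 29.5 ± 24.6 against 6.29 ± 0.604 FPKM (limma adjusted p = 0.0921), with 12.1 FPKM in control 1 and 46.9 in control 2, and the chaperone FKBP10 was 23.3 ± 5.77 against 13.4 ± 0.922 FPKM (limma adjusted p = 0.0836). Fibrillar collagens and stromal matrix did not pass (camera adjusted p = 0.666, with a median of 0.13 and a mean of -0.01; higher without control 2, adjusted p = 0.0303, and 0.676 with an estimated correlation); of 20 members FBN1 rose 2.29-fold and COL6A2 fell, 2.65-fold lower. COL1A1 was 181 ± 116 against 185 ± 53.8 FPKM (limma adjusted p = 0.838), with 98.8 and 262 FPKM in the 2 controls, and the sign of its difference turned in 3 settings. COL1A2 was 3.20 ± 0.629 against 1.45 ± 0.382 FPKM (limma adjusted p = 0.0683). Contractile and activation markers did not pass as a list (camera adjusted p = 0.573). Among them MYLK was 1.16 ± 0.255 against 2.42 ± 0.154 FPKM (limma adjusted p = 0.0536), TPM2 71.3 ± 15.1 against 26.2 ± 20.9 FPKM (limma adjusted p = 0.123), and TIMP1 118 ± 54.1 against 72.4 ± 7.28 FPKM (limma adjusted p = 0.241). TPM2 differed among the siLIX1L libraries, with 14.7, 13.6 and 50.3 FPKM in siLIX1L 1, 2 and 3. ACTA2, which encodes α smooth muscle actin, was below the FPKM minimum at 0.661 ± 0.0455 against 0.190 ± 0.0629 FPKM and was called lower by edgeR on the recovered reads (log2 fold change -1.80, adjusted p = 0.0497).

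Early targets of TGF-β did not pass (camera adjusted p = 0.124; lower in 2 of 14 other settings, none with an estimated correlation), though TGFBR2, a TGF-β receptor (2.60-fold higher), and SMURF2, a ubiquitin ligase (2.43-fold higher), rose. Neither did metalloproteinases and their inhibitors (camera adjusted p = 0.969, median -0.10 and mean 0.09), where MMP19 fell, 2.28-fold lower. Quiescent stellate cell genes did not pass either (camera adjusted p = 0.359); NGFR was 3.61 ± 1.88 against 0.911 ± 0.346 FPKM (limma adjusted p = 0.0671) and BAMBI 8.48 ± 1.83 against 5.82 ± 0.439 FPKM (limma adjusted p = 0.154). YAP/TEAD targets did not pass (camera adjusted p = 0.826), and 1 of their 17 members, NT5E, rose 2.25-fold.

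DDIT4, an inhibitor of mTORC1, fell from 18.2 ± 0.336 to 5.88 ± 0.491 FPKM in the list of the unfolded protein and integrated stress response (camera adjusted p = 0.0154; adjusted p = 0.620 with an estimated correlation). The repair gene DDB2 fell in the p53 list, from 2.06 ± 0.197 to 0.885 ± 0.138 FPKM (camera adjusted p = 0.0228; adjusted p = 0.418 with an estimated correlation), and ADM, adrenomedullin, 4.57-fold lower, fell in the list of glycolysis and hypoxia (camera adjusted p = 0.0230; adjusted p = 0.638 with an estimated correlation). Without control 1 the stress response and p53 lists did not pass (camera adjusted p = 0.569 and 0.265), and without control 2 the glycolysis list did not and its direction turned (camera adjusted p = 0.473). Of 14 other settings in all, the stress response list passed in 11, p53 in 10 and glycolysis in 11. Ribosomal proteins had 59 of 69 members negative (camera adjusted p = 5.77e-06; adjusted p = 0.638 with an estimated correlation) and oxidative phosphorylation 35 of 38 (camera adjusted p = 7.50e-04; adjusted p = 0.638 with an estimated correlation), with no member of either past the threshold. RPL10 was 15.2 ± 0.110 against 8.34 ± 0.549 FPKM (limma adjusted p = 0.0503), RPLP1 117 ± 17.9 against 51.3 ± 14.1 FPKM (limma adjusted p = 0.0641), NDUFS8 27.5 ± 3.15 against 19.1 ± 1.77 FPKM (limma adjusted p = 0.130) and COX6C 2.07 ± 0.391 against 1.34 ± 0.209 FPKM (limma adjusted p = 0.140). Both lists missed the camera threshold without control 2 (adjusted p = 0.473 and 0.250) and with the length and GC trend removed (adjusted p = 0.197 and 0.337), and the ribosomal list also with quantile normalization (adjusted p = 0.636). Ribosomal protein genes also have many pseudogenes that can share their reads.

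The remaining lists did not pass camera: apoptosis regulators (adjusted p = 0.494), fatty acid synthesis and lipid droplets (adjusted p = 0.983), binding of AU-rich elements and mRNA decay (adjusted p = 0.0507), NRF2 and oxidative stress (adjusted p = 0.126), and cholangiocyte and epithelial markers (adjusted p = 0.522). In other settings the mRNA decay list passed, higher, in 5 of 14 (adjusted p = 1.47e-04 without the minimum level and 0.00182 with edgeR's values, against 0.545 with the length and GC trend removed), and the NRF2 list, higher, in 3, none of them with an estimated correlation. In the mRNA decay list, 15 of 18 members had positive differences, among them the deadenylase CNOT7 at 6.002 ± 0.550 against 11.3 ± 0.881 FPKM (limma adjusted p = 0.0517) and the decapping factor EDC4 at 4.83 ± 0.143 against 8.51 ± 0.0462 FPKM (limma adjusted p = 0.0526). BAX was 13.7 ± 0.659 against 7.69 ± 0.357 FPKM (limma adjusted p = 0.0526), XIAP 0.793 ± 0.477 against 1.57 ± 0.223 FPKM (limma adjusted p = 0.124), PNPLA2 11.2 ± 0.928 against 7.48 ± 0.455 FPKM (limma adjusted p = 0.0969) and AGPAT2 7.67 ± 1.27 against 5.03 ± 0.533 FPKM (limma adjusted p = 0.112). EPHX1 was 1.27 ± 0.0452 against 0.718 ± 0.0531 FPKM (limma adjusted p = 0.0678) and GCLM 2.23 ± 0.783 against 4.44 ± 0.833 FPKM (limma adjusted p = 0.0894). Markers of hepatocytes, macrophages and endothelium had 0, 1 and 2 members above the minimum: CD14 at 11.3 ± 9.63 against 3.22 ± 0.788 FPKM, EGFL7 at 4.73 ± 2.21 against 1.77 ± 0.206 FPKM and ENG at 3.85 ± 0.331 against 4.12 ± 0.717 FPKM, none past the limma threshold (adjusted p = 0.159, 0.0731 and 0.813). SOX9 and MUC1 of the epithelial list had limma adjusted p = 0.103 and 0.202.

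**Figure D3:**
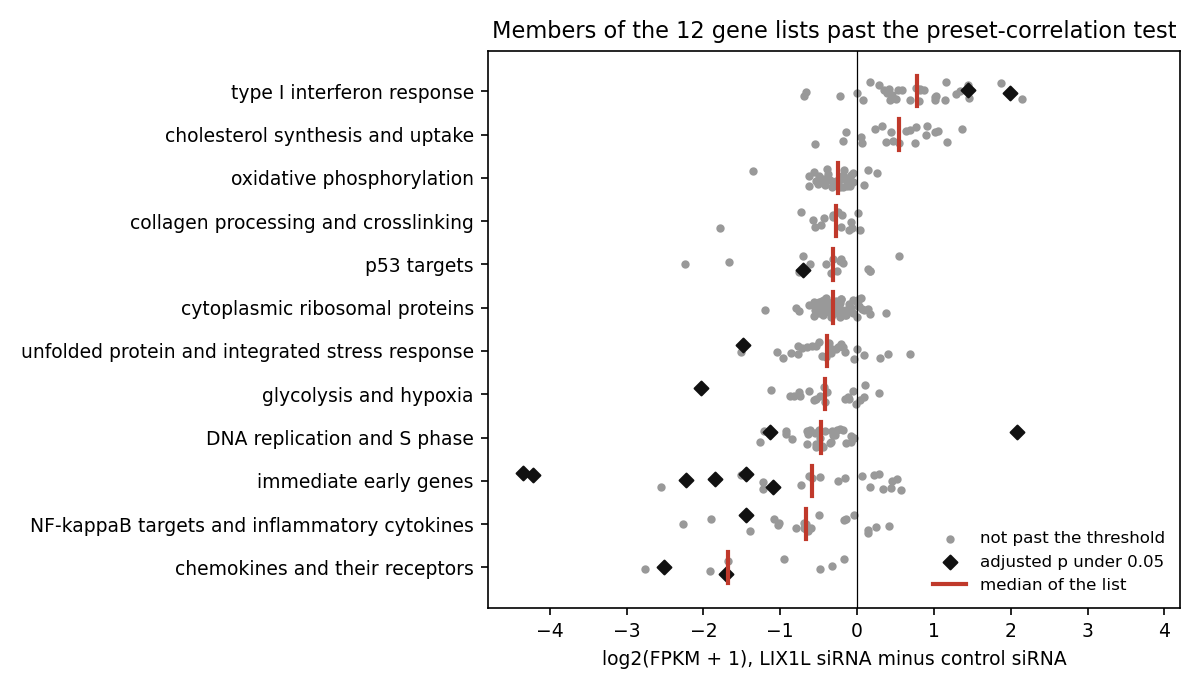
Difference in log2(FPKM + 1) between LIX1L siRNA and control siRNA (horizontal axis) for each measured member of the 12 gene lists past the camera test at its preset correlation. Diamonds are genes past limma's adjusted p of 0.05, dots the other members and red bars list medians, from -1.67 for chemokines and their receptors to 0.78 for the interferon response.

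The 3 siLIX1L libraries were not alike in which 3′ UTRs went with lower levels. Over 12885 genes, each of 15960 heptamers was scored by the difference in log2 RPM of genes whose 3′ UTR holds it, with 3′ UTR length, GC content, transcript length and level in the model. In siLIX1L 1 minus control 1 the lowest was ACTGATG (z = -11.8, coefficient -0.20 over 1707 genes), and it was again the lowest in siLIX1L 2 minus control 2 (z = -11.8), which shares no library with the first. SiLIX1L 1 and 2 were nearly alike (biological coefficient of variation 6.30%), so this is not an independent repeat. In siLIX1L 3 minus control 2 its z was -1.08, and the lowest was CACTCCT (z = -7.68, coefficient -0.15 over 1754 genes), which had z = 0.96 in siLIX1L 1 minus control 1. In siLIX1L 3 minus control 1 the lowest was ACTCCTA (z = -7.98), which the LIX1L transcript does not hold, and CACTCCT ranked 4 (z = -7.08). In siLIX1L 3 minus siLIX1L 1, with no control in the difference, the z was 16.2 for ACTGATG and -10.8 for CACTCCT, the lowest. Both heptamers occur once in the longest coding transcript of LIX1L: ACTGATG in exon 3, upstream of the 3′ UTR (GRCh38 chromosome 1, 145942757 to 145942763), and CACTCCT in exon 6, in the 3′ UTR (145933665 to 145933671). The LIX1L transcript holds 18.7% of all 16384 heptamers. The CCL20 transcript holds neither. Of the genes named as the largest changes, CLDN11, DUSP1 and CCN3 hold ACTGATG and CCND1 holds CACTCCT in the 3′ UTR. Of the 72 fallen genes with a 3′ UTR to search, 5 held ACTGATG (6.94%), against 11.2% of the genes not past the threshold (two-sided Fisher's exact p = 0.345), and of the 48 that rose 8 did (16.7%, p = 0.246). Unlike the scan, these tests did not adjust for 3′ UTR length, and the calls rest on siLIX1L 3 as well. They therefore do not show whether sites contributed to the calls.

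**Figure D4:**
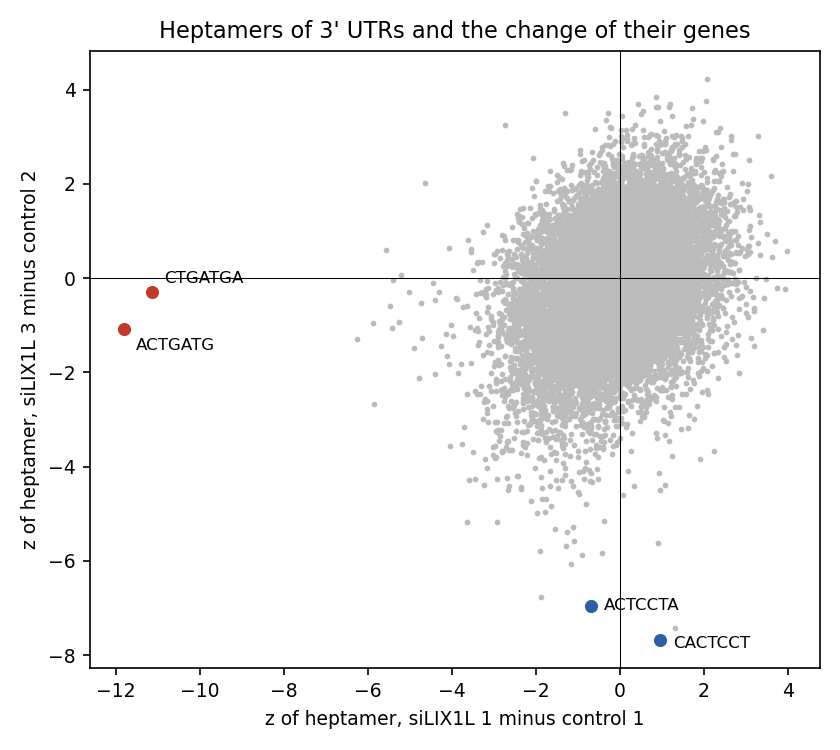
Score (z) of each of 15960 heptamers of 3′ UTRs in siLIX1L 1 minus control 1 (horizontal axis) and in siLIX1L 3 minus control 2 (vertical axis), a pair of differences that share no library; negative values mean lower levels of genes with the heptamer. ACTGATG lies at -11.8 and -1.08, and CACTCCT at 0.96 and -7.68.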

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

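EdgeR, DESeq2, the averaging of siLIX1L 1 and 2 and the trend removal were chosen after seeing the data; the other settings were planned. Leaving out 1 library at a time gave 0 to 1650 genes past the threshold in limma against 121 (0 without siLIX1L 1, 2 or 3, 1650 without control 1, 337 without control 2); fits without a control assume that the lone control varies like the other group. The count was 0 without a minimum level (16905 genes tested) and 0 with siLIX1L 1 and 2 averaged, where 3407 and 976 genes had an unadjusted p under 0.05; the second has 1 sample fewer. It was 2 with the length and GC trend removed, where the p of the called genes rose, and 233 with quantile normalization and 1673 with DESeq2, where the cause was not tested. The other counts, 94 to 156, were within 1.5 times. Calls that fell were 60.3% of all in the main test, 53.2% with quantile normalization and 77.7% with the block.

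LIX1L stayed lower throughout, by -0.75 to -0.99 with 1 library left out, but did not pass limma's threshold without a minimum (-0.87, adjusted p = 0.103), with siLIX1L 1 and 2 averaged (-0.89, 0.168), with the trend removed (-1.02, 0.0550) or without siLIX1L 1, 2 or 3 (-0.89, -0.90 and -0.82); its adjusted p ranged from 9.46e-09 to 0.230, and a minimum of 5 FPKM leaves it out. CCL20 was -0.31 to -0.48 with 1 library left out, -1.87 with a pseudocount of 0.1, -4.20 with edgeR and -4.23 with DESeq2, scales that compress low values less. The 12 lists past camera became 9 to 13 in other settings and 0 with an estimated correlation. COL1A1, not past the threshold, changed sign with the replicate block (-0.064) and ranged from -0.54 to 0.86 with 1 library left out (-0.54 without control 1, -0.064 without siLIX1L 3). DESeq2 also had more false calls on simulated data, where libraries were independent (32 of 180), than limma (12 of 143) or edgeR (16 of 145).

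Equal replicate numbers in the labels do not show a shared culture, and the differences of replicates 1 and 2 in the 2 groups had r = -0.23 across genes, so pairing was not assumed. With the replicate block, 94 genes passed, 21 higher and 73 lower, of which 44 were among the 121. Depth limits CCL20, with 10 reads in all after LIX1L siRNA.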

Other observations

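The tests below were all chosen after the data had been examined. Tests on ACTGATG in other libraries, on 3′ UTR composition and on sites upstream of the 3′ UTR were set before their results were seen. So were those on CCL20 and on sites in the lists that fell. All of these name ACTGATG, which the scan had found by then. The test on single control libraries was set before its result for 4 lists together and split after that result was seen.

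The 13 mitochondrially encoded protein genes, parts of the respiratory chain, all had negative differences after LIX1L siRNA, with a median of -1.19 on the log2(FPKM + 1) scale. None passed limma's threshold. The lowest was MT-CO3, at 4313 against 1158 FPKM (-1.82, SE 0.33, limma adjusted p = 0.0503). With quantile normalization 10 of the 13 were negative, with a median of -0.38. Their share of reads was 2.24 and 3.35% in the controls and 1.08 to 1.29% in the siLIX1L libraries. Of 28 histone genes measured, 18 had negative differences, 17 with quantile normalization. The linker histones H1-2 and H1-4 fell, H1-2 from 184.9 to 63.5 FPKM. These families were picked after their values were seen.

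Genes with ACTGATG in the 3′ UTR were lower in siLIX1L 1 and 2. In siLIX1L 1 minus control 1 the median adjusted difference was -0.22 (95% bootstrap interval -0.27 to -0.16) for the 509 genes with ACTGATGA, -0.04 for 1198 genes with ACTGATG not followed by A, and 0.06 for 8101 genes without the core, as for sites paired with the seed of a small RNA; this difference replaced that of the group means after siLIX1L 3 was seen to lack the signal. The test of a composition bias of 3′ UTRs used 615 other heptamers of the same bases that share no 5 bases in a row with ACTGATG. Their lowest z was -4.38 in the comparison of the group means, against -8.45 for ACTGATG. CTGATGA and AGCTGAT, of the same bases but overlapping it, had -7.67 and -4.44. ACTGATG was the lowest of all heptamers in that comparison, so its place below the 615 was fixed in advance. This test therefore cannot decide on a composition bias. Genes with ACTGATG upstream of the 3′ UTR (in the 5′ UTR or coding sequence, where the test had been set for the coding sequence alone) were lower too. Their coefficient was -0.10 against -0.14 in the group means, 2.02 standard errors apart. More than 2 had been set as arguing against an equal effect of sites anywhere in the transcript. The margin is slight and the standard errors take genes as independent, so this does not settle the question. In siLIX1L 1 minus control 1, used after the data were seen, the gap was wider, at -0.13 against -0.20 (difference 0.077, SE 0.023). Repression by the LIX1L siRNA through its seed, as set before this result was seen, predicted ACTGATG among the lowest heptamers in siLIX1L 3 minus control 2. It ranked 3591 from the lowest there, which argues against 1 such seed acting in all 3 libraries. This does not tell another siRNA in siLIX1L 3 from a signal in siLIX1L 1 and 2 that is not from a seed. ACTGATG or CACTCCT sites in CCL20 as the direct cause of its fall are argued against by 0 copies of either in its longest coding transcript. Sites of other heptamers in CCL20 and effects through other genes were not tested. An siRNA with another seed in siLIX1L 3 was tested in 2 random sets of genes. The heptamers lowest against control 2 in each set ranked only 1167 and 46 against control 1 in the other set. Of these heptamers 1, ACTCCTT, shares 6 bases with CACTCCT. Both ranks missed the place set for this explanation, so the result goes against it. CACTCCT, picked in siLIX1L 3 minus control 2, ranked 5 or better in each set against either control. Genes with CACTCCTA were lower (median -0.20) than those with CACTCCT not followed by A (-0.08). Genes with ACTCCTA without the base before had a median of -0.11. The library and genes here are those CACTCCT was picked in, so these values do not offset the test. The labels do not name the siRNAs, so the question is not settled.

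Fold changes followed transcript length, with Spearman's rho of 0.47 across genes (genes are not independent replicates), a median of -0.25 for transcripts of up to 2.04 kb and 0.21 for those of 4.62 kb or longer. Some libraries of the same group differed in this way too: rho was -0.24 for control 2 minus control 1 and 0.54 for siLIX1L 2 minus siLIX1L 1, but 0.04 for siLIX1L 3 minus siLIX1L 1, so RNA quality or library preparation may account for part of it. The medians for the same short and long transcripts were 0.12 and -0.16 in control 2 minus control 1. They were -0.11 and 0.05 in siLIX1L 2 minus siLIX1L 1, a smaller gap than between the groups despite the higher rho. In siLIX1L 3 minus siLIX1L 1 they were -0.05 and -0.03. An effect of LIX1L on long transcripts was not excluded. With the trend removed, 2 of the 121 genes stayed past the threshold; the 32 named ones kept their direction, with a median size of 1.28 against 1.47 (median SE 0.17 against 0.19). The calls ended as the p of the called genes rose (median 9.20e-04 against 3.79e-04, median size over SE 6.13 against 6.71): with only their p taken from the second fit 2 passed, and with only the p of the other genes taken from it all 121 did.

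Chemokine, NF-κB and immediate early lists were lower and the interferon list higher. The length and GC trend as the whole cause is argued against, since all 4 lists still passed camera's preset-correlation test with it removed (highest adjusted p 0.00473), though none did with an estimated correlation (adjusted p 0.292 or above). Of the 4 lists, set to be tested together, the immediate early list did not pass without control 1 (adjusted p 0.0635). A cause in 1 control library alone predicts this. The chemokine, NF-κB and interferon lists, split off after this result was seen, passed camera without either control at the preset correlation (highest adjusted p 0.0142). None did with an estimated correlation (adjusted p 0.391 or above). For the chemokine and interferon lists 1 control library alone is argued against by their members' median deviations in log2 RPM. For chemokines these were 0.76 and 0.63 in the controls and -0.37, -0.46 and -0.87 in siLIX1L 1, 2 and 3. For the interferon list they were -0.67 and -0.58 against -0.01, 0.35 and 0.89. For the NF-κB list 1 control library alone stays open, as control 1 carries most of the difference. Its median was 0.69 in control 1 but -0.09 in control 2, against -0.40, -0.39 and -0.15 in the siLIX1L libraries. It stays open for the immediate early list too. That list's median was, however, 0.39 and 0.35 in the controls and -0.16, -0.003 and -0.37 in the siLIX1L libraries. Of 55 members of the 3 lower lists with a 3′ UTR to search, 4 held ACTGATG (7.27%, against 11.2% of other genes, two-sided Fisher's exact p = 0.517). That comparison did not adjust for 3′ UTR length. ACTGATG in the members' own 3′ UTRs as the whole source is argued against by the 51 without it. Their median was -0.66 (95% bootstrap interval -1.03 to -0.32), though the lists were picked as lower and the interval takes genes as independent. An effect of sites in other genes that act on these members was not tested. A response to less LIX1L remains possible, and so does a difference between cultures at harvest or a response to the siRNA duplexes, neither of which the labels allow to be tested.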
